A study of Homo sapiens with 12 samples.

How the data were processed

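RNA was sequenced from 12 libraries of the human hepatoma line HepG2: 4 stable lines, each seeded in 3 wells. Per the labels' protocols, cells were transfected by lipofection with an empty or a ZHX3-directed CRISPR vector and selected with blasticidin from 48 h after transfection, RNA was extracted with a column kit, and libraries were made with a NEBNext Ultra II kit. The deposited values are whole-number read counts per gene symbol, and per the submitters' processing notes STAR, featureCounts and the hg38 genome were used. Their versions, the gene annotation, the strand setting, the handling of reads that map to several places and whether reads or read pairs were counted are not given in the sources used here. Reads of overlapping or antisense genes therefore could not be told apart with certainty, and counts of near-identical copies (alpha-class glutathione transferases, UGT2B genes, metallothioneins, histones, ribosomal protein genes with pseudogenes) are uncertain. The table held 26485 genes, of which 21343 had at least 1 count. None of the 13 mitochondrially encoded genes of the list fixed for them was in the table, so that list was not tested. Library totals ranged from 50864744 to 65428204 counts, and the 10 highest genes of a library took 9.53% to 10.5% of its counts.

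Samples were grouped by their titles into Empty, Z2, Z5 and Z9. Wells of 1 line are the replicates. The replicate letters were not used for pairing. Counts of wells of a line differed by 6.17 to 44.4 times sampling noise (chi-square per degree of freedom), so no library was counted as a repeat of another. Gene symbols were matched to a RefSeq table of assembly GRCh38.p14 for biotype and position, 23758 by current symbol and 1514 by a unique synonym, leaving 1213 unmatched. Coordinates printed are from that assembly, and the exons of ZHX3 from GENCODE release 29 on GRCh38, either of which may differ from the annotation the authors used.

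Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group left 15289 genes, libraries were scaled by TMM, and a quasi-likelihood model with 4 group means was fitted robustly to all 12 libraries, so that all comparisons share 1 estimate of the spread (8 residual degrees of freedom). The common biological coefficient of variation was 0.0696. P-values were adjusted by Benjamini and Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. SE is the log2 fold change divided by the square root of the F statistic. The comparisons were each ZHX3-labelled line minus Empty, the mean of the 3 lines minus Empty, each pair of those lines, and each of them against the mean of the other 3 lines. Levels are given as CPM on TMM-scaled library sizes, with the SD over 3 wells. Counting intervals are exact conditional 95% intervals and cover counting error only.

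Before the data were examined, 41 gene lists were fixed and tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Lists needed 5 tested members, which 40 had. An estimated correlation and fry served as alternatives. Named genes followed a rule fixed at the same time: ZHX3, ZHX1 and ZHX2; among protein-coding genes called the same way in all 3 lines with a mean of at least 1 log2 CPM, the 8 higher and 8 lower with the largest smallest change over the lines; up to 5 higher and 5 lower genes per line that also differed from both other ZHX3-labelled lines; and up to 4 members per list with the smallest adjusted p. The rule gave 168 genes, of which 5 are not reported here. The others are all named, with the libraries whose omission ends a call of the mean of the 3 lines. Genes named outside the rule are marked so.

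To see what shared Empty wells produce without any effect, 20 sets of unchanged lines were simulated from 1 pooled mean per gene and the fitted dispersions. The test was also checked on simulated counts with 50 changed genes at each fold. For Z2 minus Empty, on 15145 genes, it recovered 48% of genes changed 1.25-fold, 90% at 1.5-fold and 98% at 2-fold, and 5.08% of its calls were false. For the mean of 3 lines minus Empty, on 15128 genes, it recovered 68%, 94% and 98%, with 4.76% false. Of simulated genes changed in all 3 lines, 50 at each of 4 folds, 155 were called in all 3. The camera test called the simulated shifted list and 0 of the unchanged ones. The simulated genes were drawn independently of each other, so this does not check camera where genes vary together. DESeq2 gave 11.9% false calls for Z2 minus Empty on 15289 genes.

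Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter beyond 1 count, a minimum of 1 CPM in 3 libraries, a 2-fold minimum, the replicate letter as a block, fits of only the groups compared, wells summed per line, and each library left out in turn. The limits of 2 chromosomal regions, 6 Mb of 19p and 90 Mb of 1p, were chosen after the data were seen. Counts without their genes were added then, and windows of 40 genes were laid along the chromosomes for genes of at least 2 log2 CPM. GC content and length came from the longest GENCODE transcript of each gene. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.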

Results

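Gene expression was measured by RNA sequencing in HepG2, an established human hepatoma line that makes many liver plasma proteins. The 12 libraries came from 4 stable lines. The control line, named Empty, had received an empty CRISPR vector. The 3 other lines had received vectors labelled sgZHX3-2, sgZHX3-5 and sgZHX3-9 and are named Z2, Z5 and Z9 by their labels. Each line gave 3 wells, a to c, so n = 3 wells per line, and p-values measure the spread between wells of a line and not between independently made lines. Where lines served as units, the spread is that of the 3 labelled lines, and Empty is 1 unit without a spread of its own. With 1 control line, the vectors and the history of the Empty line could not be separated. Total counts ranged from 50864744 in Empty a to 65428204 in Empty c, and 15289 genes were tested. On the principal component with 35.0% of the variance, Empty wells lay between -39.4 and -29.0 and the other 9 wells between 4.00 and 17.6.

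The series title names depletion of ZHX3, which encodes a zinc-finger and homeobox protein that acts as a transcriptional repressor, so ZHX3 was examined first. ZHX3 mRNA was 33.0 ± 0.420 CPM in Empty, 34.5 ± 0.620 in Z2, 32.9 ± 0.505 in Z5 and 34.3 ± 0.713 in Z9 (SD, n = 3 wells each), from 1680 to 2186 counts per well. The log2 fold changes against Empty were 0.061, -0.0040 and 0.054 in Z2, Z5 and Z9 (SE 0.050 each), and none passed the test (edgeR adjusted p = 0.402, 0.972 and 0.490). For the mean of the 3 lines the 95% interval ran from 0.967-fold to 1.09-fold. ZHX3 lies on chromosome 20 from 41178455 to 41317731 (GRCh38), on the minus strand. In transcript ZHX3-201, exon 4 of 5 (41202057 to 41204916) holds 2860 of 2868 coding bases. The guide positions are not given in the sources used here. A gene-level count checks neither a small insertion or deletion nor the protein, so these values leave the depletion named in the title unchecked, and the lines are described only by their labels.

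**Figure D1:**
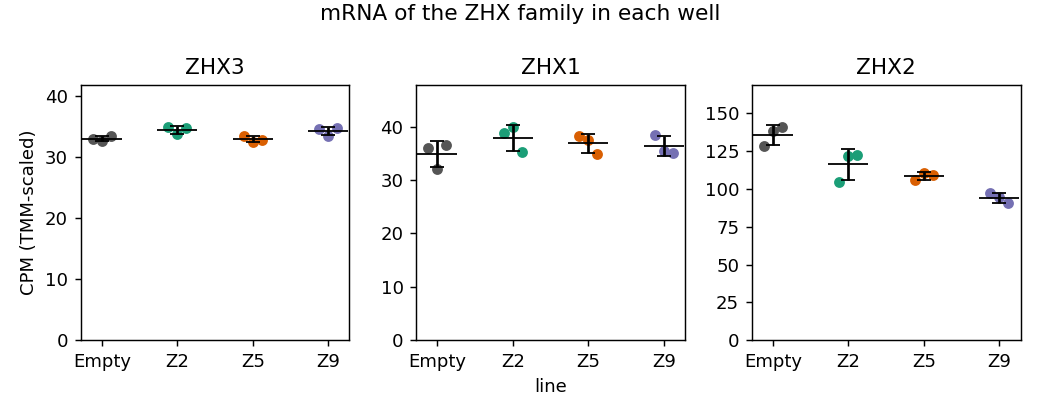
CPM of ZHX3, ZHX1 and ZHX2 (vertical axes) in each well of the 4 lines (horizontal axis), with points for wells and bars for mean ± SD of 3 wells. ZHX3 lies between 32.5 and 34.9 CPM in all 12 wells, while mean ZHX2 goes from 136 CPM in Empty to 94.2 CPM in Z9.

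Of the related genes, ZHX2 was lower in all 3 lines, with 136 ± 6.43 CPM in Empty, 116 ± 10.2 in Z2, 108 ± 2.34 in Z5 and 94.2 ± 3.30 in Z9. Its mean log2 fold change was -0.36 ± 0.048 (SE, edgeR adjusted p = 3.9e-05). ZHX1 did not pass the test (0.086 ± 0.055, edgeR adjusted p = 0.272). NFYA, a subunit of the NF-Y factor, fell (-0.18). Of 6 tested ZHX and NF-Y genes, 0 rose and 2 fell (0 and 2 adjusted over the list alone), with a median of -0.073 and a camera adjusted p of 0.274. Among genes that flank ZHX3 on 20q, of 21 tested members 3 rose and 5 fell (4 and 5 adjusted over the list alone), with a median of 0.039 and a camera adjusted p of 0.971. SGK2 (-0.64) and MYBL2 (-0.38) fell, and SERINC3 (0.20) rose. With 1 library left out, the edgeR adjusted p was not past the threshold for NFYA without Empty a (0.0642).

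The mean of the 3 labelled lines was compared with Empty. PLG, which encodes plasminogen, rose from 1.66 ± 0.525 CPM in Empty to 18.5 ± 1.49 in Z2, 22.4 ± 1.64 in Z5 and 21.7 ± 0.612 in Z9 (mean log2 fold change 3.63 ± 0.13, edgeR adjusted p = 1.9e-11). CDCA7L had 27 counts over the 3 Empty wells and 458 to 645 over the wells of each other line, a 21.9-fold ratio with a 95% counting interval of 15.0 to 33.3, which covers counting error only (fitted log2 fold change 4.41). The WNT inhibitor APCDD1 (2.82), NDUFA4L2 (2.90), the insulin-like growth factor binding protein IGFBP2 (2.56), the phospholipase PLA2G16 (2.30), the EGF receptor ligand EREG (2.35) and ABLIM3 (2.18) also rose in all 3 lines. The laminin chain LAMC3 fell from 15.1 ± 1.77 CPM in Empty to 2.28 ± 0.342 in Z2, 1.79 ± 0.189 in Z5 and 1.76 ± 0.279 in Z9 (-2.96 ± 0.097, edgeR adjusted p = 1.2e-12). The glutathione transferase GSTA1 (-2.58), the sulfotransferase CHST9 (-1.72), RTN4RL2 (-1.56), ATP10D (-1.36), the homeobox gene HOXD1 (-1.38), the KIT ligand KITLG (-1.39) and AMOT (-1.18), which encodes angiomotin, also fell in all 3. GSTA1 shares sequence with other alpha-class transferases, so its level is uncertain.

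In all, 3911 of 15289 genes differed, 1991 higher and 1920 lower, and 369 of them differed at least 2-fold, 283 higher and 86 lower. The count was 2107 without Empty a, and 1100 when wells were summed and the lines served as units.

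**Figure D2:**
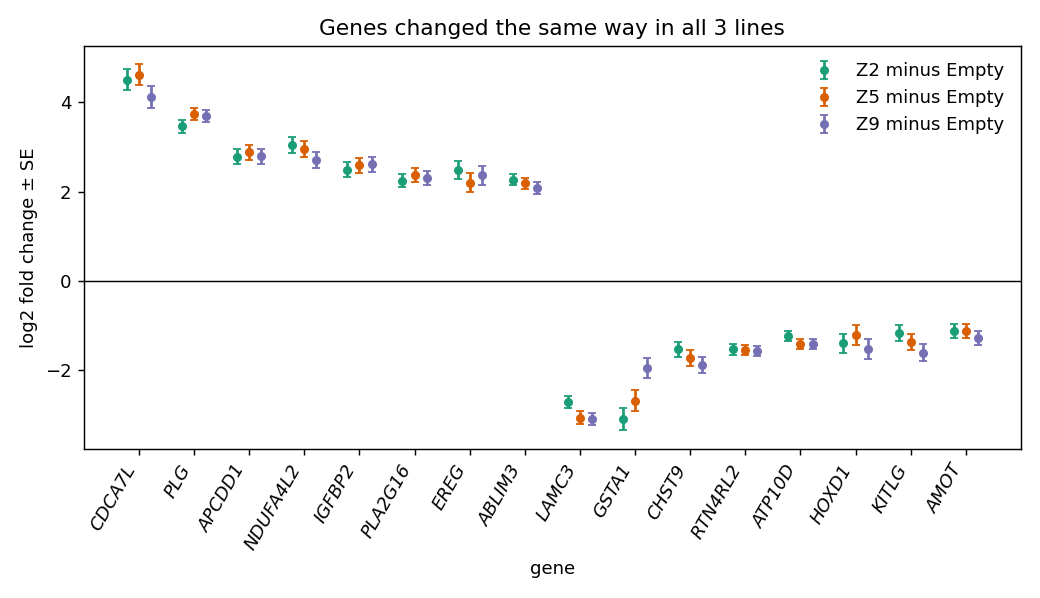
Log2 fold change ± SE (vertical axis) of the 16 genes chosen for a shared change (horizontal axis), for each line minus Empty, n = 3 wells per line. Mean changes run from 4.41 for CDCA7L to -2.96 for LAMC3, and the 3 points of each gene lie on the same side of 0.

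The lines were compared singly with Empty to ask whether they shared changes. In Z2, 3654 genes differed (1900 higher, 1754 lower), in Z5 2286 (1264 higher, 1022 lower) and in Z9 2941 (1477 higher, 1464 lower). Of these, 1343 changed the same way in all 3 lines, 762 higher and 581 lower. Independent lists of these sizes would share 15.2 higher and 11.2 lower genes, and 20 simulations of unchanged lines against the shared Empty wells gave 0. The 3 Empty wells were too few to split, so part or all of the excess may come from the shared Empty line. With the Empty wells kept together, 99 regroupings of the 9 other wells gave 893 to 1297 such genes, so most of the count did not depend on how these wells were grouped into lines. Across genes, which are not independent replicates, fold changes correlated with Pearson r = 0.865 (Spearman 0.776) for Z2 and Z5, 0.807 (0.667) for Z2 and Z9, and 0.820 (0.714) for Z5 and Z9. Simulated unchanged lines gave 0.490, 0.486 and 0.494. The covariances were 0.157, 0.152 and 0.146, against 0.0167, 0.0165 and 0.0167 simulated. The simulation drew the Empty wells from the same means as the other lines, so it held no divergence of the Empty line. Such a divergence would enter all 3 fold changes, so these values cannot tell it apart from a shared effect of the vectors. MALT1 (0.27 in Z2, -0.32 in Z9), SUSD2 (0.54 and -0.39) and GLRX (0.35 and -0.23), named after their values were seen, were the 3 genes called in opposite directions. Without Empty a the counts were 2130 in Z2, 1105 in Z5, 1720 in Z9 and 722 shared, and a fit of Z2 and Empty alone called 2390. The Z5 count was 1146 without Z5 b and 1087 without Z5 c, the shared count 874 and 871 without them, and the Z9 count 1873 without Z9 b.

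Differences among the labelled lines were then tested. Protein-coding genes with a mean of at least 1 log2 CPM were considered. By edgeR, 25 were higher and 71 lower in Z9 than in each of the other 3 lines. In Z2 and Z5 0 genes met this rule. Both of those rules need called differences between Z5 and Z2, where edgeR called 1 gene, so these counts of 0 were nearly fixed in advance. Without Z5 c edgeR called 37 genes between Z9 and Z5, so at most 37 could meet the Z9 rule there. The genes named by the Z9 rule that were higher in Z9 than in Empty were RBM23 (0.82), the lipid transporter ABCA3 (0.79), AOC2 (0.57), RPL22L1 (0.53) and the fibrinogen chain FGB (0.49). Those lower were HAVCR1 (-1.39), C19orf80 (-1.15), an older symbol of the lipoprotein lipase inhibitor ANGPTL8, PTGFRN (-0.91) and the protease inhibitor CSTB (-0.77). In the mean of the 3 lines RBM23 and AOC2 did not pass the test (0.29 and 0.19), and RBM23 passed at its highest leave-one-out value (0.57, edgeR adjusted p = 0.0187). The edgeR adjusted p missed the threshold for ABCA3 without Empty a (0.0618) and RPL22L1 without Empty b (0.0529).

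Between Z9 and Z2, 790 genes differed (299 higher in Z9, 491 lower), and between Z9 and Z5, 232 (66 higher, 166 lower). Between Z5 and Z2, edgeR called 1 gene, 1571 had an unadjusted p under 0.05, and DESeq2 called 11. That gene, named after its values were seen, was the heparan sulfate proteoglycan GPC4, at 0.034 CPM in Empty, 0.34 in Z2, 1.53 in Z5 and 1.93 in Z9 (Z5 minus Z2 2.16, edgeR adjusted p = 4.7e-04). Against the mean of the other 3 lines, Z2 differed at 1277 genes (750 higher, 527 lower), Z5 at 128 (111 higher, 17 lower) and Z9 at 1208 (552 higher, 656 lower). With the Empty wells kept together, 16 of 100 regroupings of the 9 other wells gave as many genes as Z5, so its count does not stand apart from that of other groupings. For Z2 and Z9 4 and 3 of 100 did, the real grouping included. Mixed wells reached 2142 and 2130 genes under these names, so chance was not excluded for Z2 and Z9 either.

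These counts changed when single libraries were left out, which also leaves a line with fewer wells. Between Z9 and Z2 the count was 75, 81 and 219 without Z9 b, a and c, 2399, 216 and 316 without Z2 a, b and c, 372 and 452 without Z5 b and c, and 456 and 518 without Empty b and c. Between Z9 and Z5 it was 57, 86 and 68 without Z9 a, b and c, 44 and 37 without Z5 b and c, and 653 without Z2 b, and between Z5 and Z2 it was 153 without Z2 a. For Z2 against the rest it was 2955, 273 and 539 without Z2 a, b and c, 783 without Empty a, 755 without Z5 a and 748 without Z9 b. For Z5 it was 40 and 38 without Z5 b and c and 252 without Z2 b. For Z9 it was 484, 423 and 593 without Z9 a, b and c and 793 without Z5 b. DESeq2 called 1526 genes between Z9 and Z2, 504 between Z9 and Z5 and 307 for Z5 against the rest, and fits of the pair alone called 32 between Z9 and Z2 and 664 between Z9 and Z5.

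Of 41 gene lists fixed before the data were examined, 40 could be tested, and 8 shifted in the mean of the 3 lines by camera with a preset correlation, 3 upward and 5 downward. With a correlation estimated from the data 0 lists passed, and for each of the 8 adjusted p = 0.667 with an estimated correlation. The test fry called 24 lists by its directional p. Random regroupings of the 12 libraries gave 8 or more lists in 28 of 100 cases, so the number of shifted lists does not stand apart from that of other groupings. Values after gene symbols in the paragraphs on lists are mean log2 fold changes of the 3 lines against Empty.

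Genes of cell division were lower. In the G2 and mitosis list, of 30 tested members 0 rose and 26 fell (0 and 29 adjusted over the list alone), with a median of -0.38 and a camera adjusted p of 7.1e-12 (adjusted p = 0.667 with an estimated correlation). The proliferation marker MKI67 (-0.48), KIF2C (-0.41) and CDC20 (-0.40), both on 1p, and BIRC5 (-0.45), which encodes survivin, fell. In the S phase and replication list, of 30 tested members 0 rose and 22 fell (0 and 24 adjusted over the list alone), with a median of -0.33 and a camera adjusted p of 4.1e-09 (adjusted p = 0.667 with an estimated correlation). CDC45 (-0.59), UHRF1 (-0.86), which lies in the 19p region, the licensing factor CDC6 (-0.63) and the helicase subunit MCM3 (-0.44) fell. Mean centred log2 CPM over both lists was 0.44, 0.25 and 0.11 in Empty a, b and c, and between -0.18 and 0.057 in the 9 other wells. Without Empty a the medians of the lists were -0.30 and -0.25. Of 17 tested replication-dependent histones, whose mRNAs mostly lack poly(A) tails and share sequence, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.053 and a camera adjusted p of 0.320. HIST1H2BK (1.10), HIST1H2BD (0.42) and HIST1H2AC (0.27) rose, as did HIST1H2AG, with 14 counts over the Empty wells (2.88-fold ratio, 95% counting interval 1.65 to 5.44). By edgeR adjusted p, the call was lost for HIST1H2AC without Empty a or b (up to 0.0853) and HIST1H2AG without Empty a or c (up to 0.0878).

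Secreted liver products moved in both directions. Albumin mRNA (ALB) was at 17530 ± 797 CPM in Empty, 11520 ± 790 in Z2, 11480 ± 635 in Z5 and 11970 ± 496 in Z9, and fell (-0.59 ± 0.052, edgeR adjusted p = 3.1e-07). Vitronectin, VTN (0.74), SERPINA3 (0.75) and haptoglobin, HP (0.64), rose. Of 23 tested plasma proteins, 10 rose and 5 fell (10 and 5 adjusted over the list alone), with a median of 0.064 and a camera adjusted p of 0.274. In the coagulation list, of 18 tested members 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 9.2e-04 (adjusted p = 0.667 with an estimated correlation). PLG, whose product dissolves fibrin, the fibrinogen chains FGA (0.46) and FGG (0.38), and the fibrinolysis inhibitor CPB2 (0.57) rose. In the complement list, of 16 tested members 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.25 and a camera adjusted p of 0.00721 (adjusted p = 0.667 with an estimated correlation), and the camera adjusted p was 0.0856 without genes of the 19p and 1p regions. It was 0.0570 with the lines as units and 0.0782 in Z9 alone (camera). C8B (1.05) on 1p, CFI (0.43), the central component C3 (0.48) and CFB (0.41) rose. In the apolipoprotein list, of 23 tested members 4 rose and 6 fell (6 and 6 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.858. APOA4 (-1.07) and C19orf80 (-0.83) fell, and MTTP (0.39), which loads lipid onto apolipoprotein B, and the lipase inhibitor ANGPTL4 (0.68) rose. In the inflammatory and acute phase list, of 18 tested members 6 rose and 4 fell (7 and 5 adjusted over the list alone), with a median of 0.10 and a camera adjusted p of 0.426. SOCS3 (0.75) and CCL20 (0.21) rose with haptoglobin, and NFKB1 (-0.22) fell.

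Cholesterol synthesis genes were lower in Z2 and Z9. In this list, of 23 tested members 1 rose and 14 fell (1 and 16 adjusted over the list alone), with a median of -0.23 and a camera adjusted p of 6.6e-05 (adjusted p = 0.667 with an estimated correlation). The single-line medians were -0.16 in Z2 (camera adjusted p = 0.00642), -0.011 in Z5, where the list did not pass (camera adjusted p = 0.836), and -0.47 in Z9 (camera adjusted p = 1.2e-11). With an estimated correlation the adjusted p was 0.673 in Z2 and 0.689 in Z9 (camera). In Z5 1 member was higher and 2 lower than in Empty, and in Z9 18 were lower. With the lines as units the list did not pass (camera adjusted p = 0.0633). The difference itself was tested, and 16 members were lower in Z9 than in Z5 (median -0.47, camera adjusted p = 4.6e-25, adjusted p = 0.424 with an estimated correlation). Against Z2, 12 were lower in Z9 (median -0.33, camera adjusted p = 3.2e-10, adjusted p = 0.748 with an estimated correlation). HSD17B7 (-0.40) and ACAT2 (-0.36) fell in the mean of the 3 lines. INSIG1, which retains SREBP precursors in the endoplasmic reticulum, was the member that rose, from 5 counts over the Empty wells, all in 1 well, to 48 to 75 over the wells of each other line (13.4-fold ratio, 95% counting interval 5.63 to 41.7). The annotation used for counting is not given, so its level is uncertain.

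**Figure D3:**
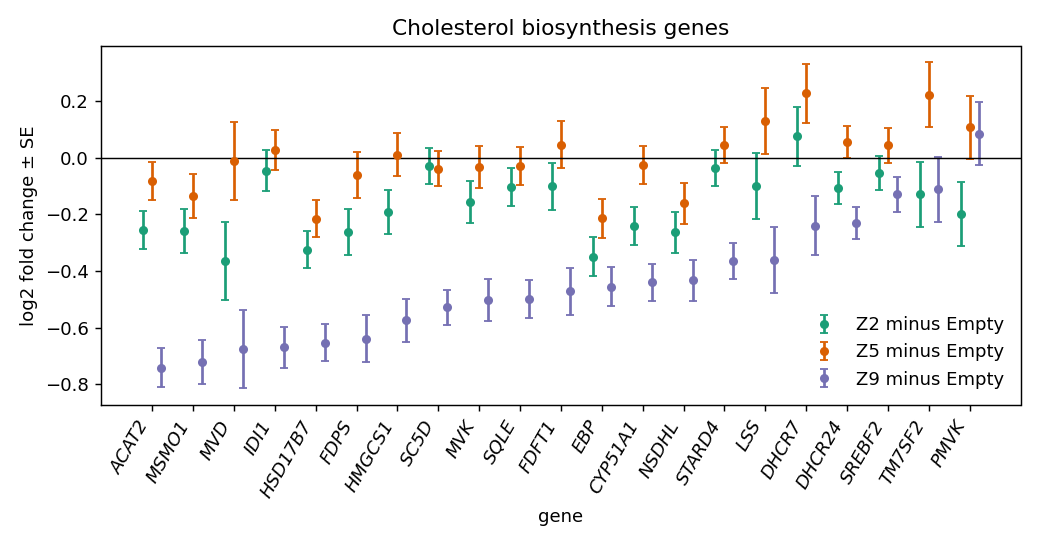
Log2 fold change ± SE (vertical axis) against Empty of the cholesterol biosynthesis genes reported here (horizontal axis), for each line, n = 3 wells per line, leaving out INSIG1, which is near the floor in Empty. Values for ACAT2 are -0.74 in Z9, -0.082 in Z5 and -0.26 in Z2.

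Of 21 tested genes of fatty acid and triglyceride synthesis, 1 rose and 6 fell (1 and 6 adjusted over the list alone), with a median of -0.067 and a camera adjusted p of 0.140, and the list passed camera without Empty a (adjusted p = 0.0126). In Z9 alone 1 rose and 9 fell, with a median of -0.22 (camera adjusted p = 6.2e-04, adjusted p = 0.689 with an estimated correlation), and in Z2 and Z5 the list did not pass (camera adjusted p = 0.314 and 0.921). The elongase ELOVL5 (0.51) rose, and DGAT1 (-0.39), PNPLA3 (-0.40) and DGAT2 (-0.29) fell. In the fatty acid oxidation list, of 23 tested members 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a median of 0.044 and a camera adjusted p of 0.859. ECI2 (-0.16), ETFA (-0.15) and ACOT1 (-0.28), which has a close paralog, fell. In the lipid droplet list, of 15 tested members 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of 0.022 and a camera adjusted p of 0.943, where camera's direction was downward and the median upward. CD36 (-0.97) and PLIN3 (-0.30), which lies in the 19p region, fell, and HSD17B11 (0.33) and the lipase PNPLA2 (0.19) rose. With 1 library left out, the edgeR adjusted p was not past the threshold for ECI2 without Empty b (0.0970), ETFA without Empty a or b (up to 0.164), ACOT1 without Empty b or c (up to 0.0798) and PNPLA2 without Empty a (0.0562).

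Hypoxia targets were higher in Z2 and Z5. In this list, of 20 tested members 10 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.00262 (adjusted p = 0.667 with an estimated correlation). The list passed in Z2 alone (camera adjusted p = 3.8e-05, adjusted p = 0.665 with an estimated correlation) and in Z5 alone (camera adjusted p = 0.00202, adjusted p = 0.677 with an estimated correlation). In Z9 alone 4 rose and 1 fell, with a median of 0.054, and the list did not pass (camera adjusted p = 0.337). The list was lower in Z9 than in Z2 and Z5 by camera (adjusted p = 3.0e-06 and 0.00257), with adjusted p = 0.748 and 0.609 with an estimated correlation. The prolyl hydroxylase EGLN3 (1.28), the glucose transporter SLC2A1 (0.36) on 1p, the collagen hydroxylase P4HA2 (0.30) and MXI1 (0.37) rose. In the glycolysis list, of 20 tested members 5 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.096 and a camera adjusted p of 0.157, and the list passed camera without Empty b (adjusted p = 0.0262). The list had a median of 0.035 without Empty a and did not pass there (camera adjusted p = 0.338). It passed in Z2 alone (median 0.17, camera adjusted p = 0.0258, adjusted p = 0.689 with an estimated correlation) and in Z5 alone (0.14, camera adjusted p = 0.0198, adjusted p = 0.677 with an estimated correlation), and not in Z9 (-0.012, camera adjusted p = 0.863). The hexokinase HK1 (1.10), PFKFB3 (0.23) and PFKM (0.33) rose with SLC2A1. In the gluconeogenesis list, of 18 tested members 6 rose and 3 fell (6 and 3 adjusted over the list alone), with a median of 0.023 and a camera adjusted p of 0.496. The glucose-6-phosphatase gene G6PC (1.57), the coactivator PPARGC1A (0.50) and pyruvate carboxylase, PC (0.30), rose, and the glucose transporter SLC2A2 (-0.31) fell. Of 28 tested nuclear oxidative phosphorylation genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone), with a median of -0.079 and a camera adjusted p of 0.00443 (adjusted p = 0.667 with an estimated correlation). In Z2 and Z5 alone this list did not pass (camera adjusted p = 0.0675 and 0.0832). SDHB (-0.23) on 1p and the ATP synthase subunits ATP5F1 (-0.15), ATP5A1 (-0.13) and ATP5B (-0.12) fell. In the urea cycle and amino acid list, of 17 tested members 2 rose and 8 fell (4 and 9 adjusted over the list alone), with a median of -0.13 and a camera adjusted p of 0.320. Glutamine synthetase, GLUL (0.36), rose, and arginase, ARG1 (-0.88), and glutamate dehydrogenase, GLUD1 (-0.20), fell. The edgeR adjusted p missed the threshold for PFKM without Empty a or c, Z2 c, Z5 b or c or Z9 b (up to 0.158), ATP5F1 without Empty a (0.0620), ATP5A1 without Empty a or b (up to 0.133) and ATP5B without Empty a or b (up to 0.168).

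NRF2 targets were lower in the mean of the 3 lines. In this list, of 20 tested members 0 rose and 7 fell (1 and 7 adjusted over the list alone), with a median of -0.11 and a camera adjusted p of 0.00469 (adjusted p = 0.667 with an estimated correlation). In Z9 alone the list did not pass (median -0.055, camera adjusted p = 0.0915), and neither did its difference from Z2 or Z5 (camera adjusted p = 0.0569 and 0.193). The conjugate exporter ABCC3 (-0.46), AKR1B10 (-1.16), NQO1 (-0.37) and TXNRD1 (-0.22) fell. In the cytochrome P450 and phase I list, of 16 tested members 7 rose and 4 fell (8 and 4 adjusted over the list alone), with a median of 0.33 and a camera adjusted p of 0.102, and the list passed camera without Empty c (adjusted p = 0.0280). CYP2J2 (1.26) on 1p and FMO5 (0.58) rose, and ALDH1A1 (-0.60) and CES1 (-0.91) fell. Of 15 tested conjugating enzymes, 2 rose and 6 fell (3 and 8 adjusted over the list alone), with a median of -0.14 and a camera adjusted p of 0.245. The similar genes UGT2B4 (1.17) and UGT2B7 (-0.66), whose reads may be shared, rose and fell, and GSTA1 and SULT2A1 (-0.18) fell. In the bile acid list, of 21 tested members 4 rose and 8 fell (7 and 8 adjusted over the list alone), with a median of -0.058 and a camera adjusted p of 0.534. The conjugating enzyme BAAT (1.30) and the phospholipid exporter ABCB4 (0.62) rose, and ABCC3 and HSD3B7 (-0.37) fell. In the metallothionein and iron list, of 19 tested members 2 rose and 7 fell (3 and 7 adjusted over the list alone), with a median of -0.036 and a camera adjusted p of 0.336. TFR2 (0.49) rose, and HFE (-0.62) and ferritin light chain, FTL (-0.25), fell. MT1M, a metallothionein with close paralogs, fell from 90 counts over the Empty wells to 14 to 24 over the wells of each other line (-2.13).

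**Figure D4:**
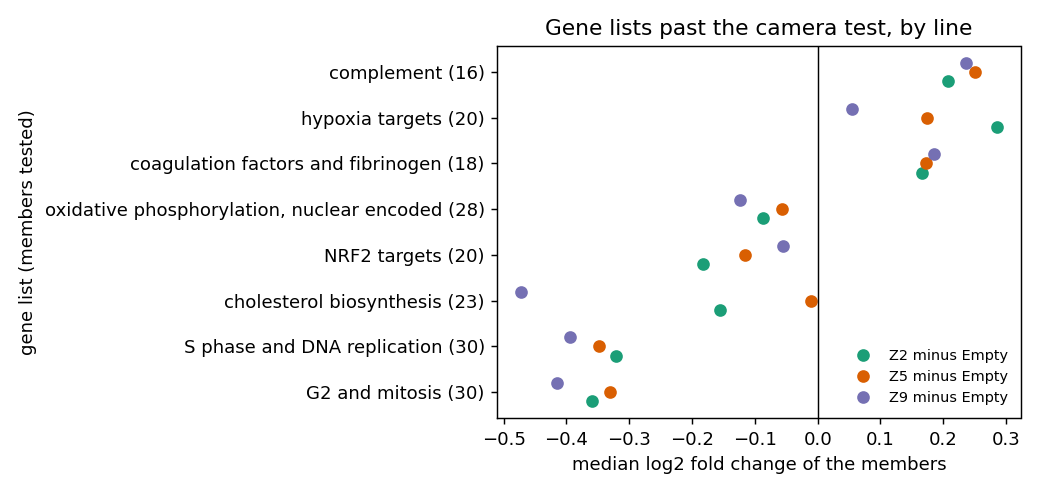
Median log2 fold change against Empty (horizontal axis) of the members of the 8 lists past the camera test (vertical axis, members tested in brackets), 1 point per line. Medians for G2 and mitosis are -0.36, -0.33 and -0.41 in Z2, Z5 and Z9, and those for cholesterol biosynthesis go from -0.011 in Z5 to -0.47 in Z9.

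Liver identity genes changed singly, and their lists did not pass. Of 27 tested hepatocyte transcription factors, 4 rose and 9 fell (5 and 12 adjusted over the list alone), with a median of -0.068 and a camera adjusted p of 0.233. NR2F1 (0.37) and TBX3 (0.25) rose, and GATA6 (-0.57) and NR0B2 (-0.45) on 1p fell. In the fetal liver and oncofetal list, of 13 tested members 3 rose and 5 fell (3 and 5 adjusted over the list alone), with a median of -0.057 and a camera adjusted p of 0.730. CD24 (1.41) and DLK1 (0.47) rose, and LIN28B (-0.70) and HMGA2 (-0.25) fell. In the WNT list, of 18 tested members 8 rose and 4 fell (8 and 4 adjusted over the list alone), with a median of 0.091 and a camera adjusted p of 0.140, and the list passed camera with a minimum of 1 CPM in 3 libraries (adjusted p = 0.0474) and without Empty a (adjusted p = 0.0310). APCDD1, the WNT deacylase NOTUM (0.56), GLUL and KREMEN1 (0.44) rose. In the YAP list, of 19 tested members 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.051 and a camera adjusted p of 0.336. NT5E (1.04), ARHGEF17 (0.17) and CRIM1 (0.16) rose, and ANKRD1 (-0.89) fell. By edgeR adjusted p, the call was lost for ARHGEF17 without Empty a (0.0697), CRIM1 without Empty a or c, Z5 b or c or Z9 b or c (up to 0.168) and ANKRD1 without Empty a or b, Z2 a or c, Z5 a, b or c or Z9 b (up to 0.160). Without the low-count filter ANKRD1 also missed it (edgeR adjusted p = 0.0504).

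In the TGF-beta and mesenchymal list, of 17 tested members 1 rose and 4 fell (2 and 6 adjusted over the list alone), with a median of -0.057 and a camera adjusted p of 0.321. SPARC (0.86) rose, and TAGLN (-0.96), SNAI1 (-0.41) and SNAI2 (-2.01), with 115 counts over the Empty wells, fell. In the matrix list, of 19 tested members 5 rose and 4 fell (7 and 4 adjusted over the list alone), with a median of 0.092 and a camera adjusted p of 0.245. The protease inhibitor TIMP3 (0.84), the protease MMP2 (1.52) and COL6A1 (0.32) rose, and MMP14 (-0.55) fell. In the epithelial list, of 18 tested members 1 rose and 4 fell (2 and 5 adjusted over the list alone), with a median of 0.017 and a camera adjusted p of 0.426, where camera's direction was downward and the median upward. E-cadherin, CDH1 (-0.63), the keratin KRT8 (-0.20) and CLDN2 (-0.88) fell. Of 11 tested cholangiocyte and progenitor markers, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.16 and a camera adjusted p of 0.157. Osteopontin, SPP1 (0.87), CD24 and ITGB4 (0.28) rose, and ANXA4 (-1.11) fell. Of 8 tested hematopoietic markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.040 and a camera adjusted p of 0.651, and CD74 (0.34) rose. Of 7 tested stromal and endothelial markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of 0.077 and a camera adjusted p of 0.634, and CDH5 (1.67) rose and COL1A1 (-0.70) fell. The COL1A1 value ran from -0.87 to -0.37 with 1 library left out. Of 7 tested neural markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.261. TUBB3 (0.33) rose, as did SYT1, with 6 counts over the Empty wells (4.48-fold ratio, 95% counting interval 1.97 to 12.6). With 1 library left out, the edgeR adjusted p was not past the threshold for SNAI1 without Empty a or b (up to 0.158), ITGB4 without Empty b (0.0793), COL1A1 without Empty a, Z2 c, Z5 a or c or Z9 a or b (up to 0.390) and SYT1 without Empty a or c (up to 0.0803).

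In the p53 list, of 28 tested members 2 rose and 5 fell (4 and 6 adjusted over the list alone), with a median of -0.060 and a camera adjusted p of 0.339. GDF15 (-0.34), BTG2 (-0.23) and MDM2 (-0.15) fell, and CCNG1 (0.17) rose. Of 23 tested unfolded protein and integrated stress genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of -0.036 and a camera adjusted p of 0.858. VLDLR (0.94) and DNAJB9 (0.27) rose, and PPP1R15A (-0.30) and XBP1 (-0.13) fell. In the interferon list, of 21 tested members 2 rose and 4 fell (2 and 4 adjusted over the list alone), with a median of 0.047 and a camera adjusted p of 0.645, where camera's direction was downward and the median upward. OAS3 (-0.32), IFIH1 (-0.40) and BST2 (-0.19) fell, and IRF9 (0.20) rose. Of 16 tested immediate early genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a median of -0.072 and a camera adjusted p of 0.550. KLF4 (0.54) and IER2 (0.19) rose, and IER3 (-0.46) and EGR1 (-0.62) fell. Of 30 tested cytosolic ribosomal protein genes, 3 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.042 and a camera adjusted p of 0.299, and the list passed camera without Z2 b (adjusted p = 0.0445). RPL5 (0.14), RPS4X (0.13) and RPL14 (0.16), which have many pseudogenes, rose. The edgeR adjusted p missed the threshold for BTG2 without Empty a (0.136), MDM2 without Empty a or b (up to 0.0957), CCNG1 without Empty a or b (up to 0.0928), XBP1 without Empty a or c or Z5 b (up to 0.198), BST2 without Empty b (0.0525) and IRF9 without Empty a or b (up to 0.102). By edgeR adjusted p, the call was lost for IER2 without Empty a or c (up to 0.0765), EGR1 without Empty a or b (up to 0.124), RPL5 without Empty a or b (up to 0.104), RPS4X without Empty a, b or c, Z2 c, Z5 b or c or Z9 b or c (up to 0.198) and RPL14 without Empty a, b or c, Z2 c, Z5 a, b or c or Z9 b or c (up to 0.215). RPS4X also missed it without the low-count filter (edgeR adjusted p = 0.0612).

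Fold changes were laid out by gene position, and 2 regions were delimited after the data were seen. The 124 genes of at least 2 log2 CPM that start within 6 Mb of the 19p end had a median log2 fold change of -0.24 ± 0.013 (bootstrap SD over genes) in the mean of the 3 lines. Of these, 93.5% lay below 0, 86 fell and 3 rose. The medians were -0.30 in Z2, -0.22 in Z5 and -0.18 in Z9. By steps of 1 Mb, the median was -0.27 for genes that start from 4 Mb, -0.21 from 5 Mb (11 genes), 0.0093 from 6 Mb (13 genes) and -0.12 from 10 Mb (27 genes). The lowest window median outside the 2 regions was -0.10, also on chromosome 19. The 521 genes that start within 90 Mb of the 1p end had a median of -0.094 ± 0.0072, with 73.1% below 0, 157 lower and 29 higher. The lowest window median of this 1p region was -0.12, close to the -0.10 outside the regions, while 19p windows reached -0.27. Outside both regions 10040 genes had a median of -0.0067, with 51.6% below 0.

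**Figure D5:**
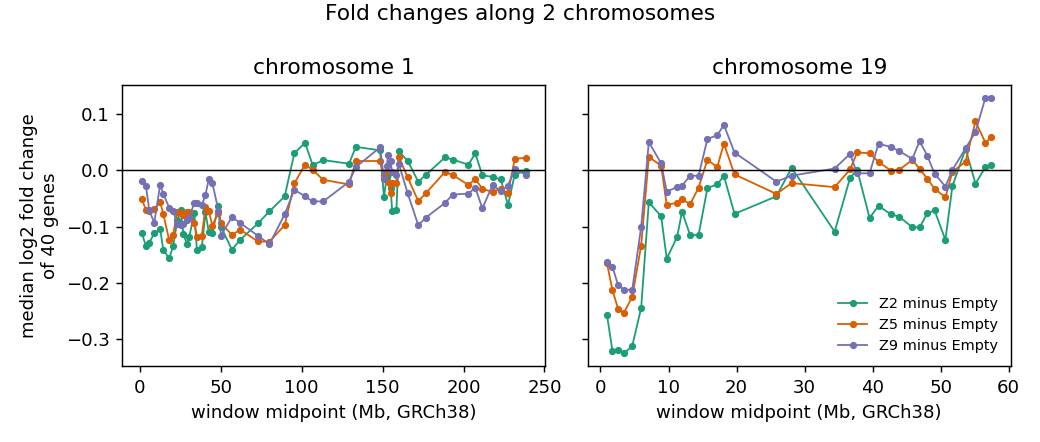
Median log2 fold change against Empty of windows of 40 neighbouring genes (vertical axis) by position in Mb (horizontal axis, GRCh38) on chromosomes 1 and 19, 1 trace per line. Windows in the first 6 Mb of chromosome 19 reach -0.33 in Z2, -0.25 in Z5 and -0.21 in Z9.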

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

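Tests of the GC content, length and expression trend, of classes of expression, of cell division genes outside the chromosomal regions and of random regroupings had their outcomes stated before they were run. The limits of the 2 regions were chosen after the data were seen, and so were the tests of the line distances, of the calls outside the regions, of the single-line 19p medians, of the growth state and of regroupings with the Empty wells kept together.

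The fold changes of the lines, each against the same Empty wells, differed at 1 gene for Z5 and Z2, 790 for Z9 and Z2, and 232 for Z9 and Z5, by edgeR tests of the difference itself. For the named genes below, the pair with the smallest adjusted p is given as a log2 difference. Between Z9 and Z5, Z9 was higher for RBM23 (0.91), ABCA3 (0.57), RPL22L1 (0.45), OAS3 (0.31) and KLF4 (0.73), and lower for HAVCR1 (-0.82), C19orf80 (-0.57), PTGFRN (-0.30), CSTB (-0.42), HSD17B7 (-0.44), ACAT2 (-0.66), PNPLA3 (-0.60) and GLUD1 (-0.26). Between Z9 and Z2, Z9 was higher for GSTA1 (1.14), AOC2 (0.59), FGB (0.36), ALDH1A1 (0.32), GDF15 (0.32) and NOTUM (0.23), and lower for ZHX2 (-0.30), DLK1 (-0.46), HMGA2 (-0.25), CFI (-0.30), SLC2A1 (-0.29), FMO5 (-0.30) and VLDLR (-0.34). Gene lists that differed between lines by camera with the preset correlation had the median log2 differences that follow. With an estimated correlation none of them passed, and by fry's directional p only cholesterol biosynthesis between Z9 and Z5 did (fry adjusted p = 0.00565). Z5 minus Z2 gave 0.15 for cholesterol biosynthesis, 0.089 for fatty acid oxidation and -0.086 for hypoxia targets. Z9 minus Z2 gave -0.19 for fetal liver genes, -0.13 for apolipoproteins, -0.33 for cholesterol biosynthesis, -0.12 for fatty acid synthesis, -0.135 for glycolysis, 0.094 for p53 targets, 0.10 for the unfolded protein response, -0.19 for hypoxia targets and 0.22 for immediate early genes. Z9 minus Z5 gave -0.12 for fetal liver genes, -0.16 for apolipoproteins, -0.47 for cholesterol biosynthesis, -0.14 for fatty acid synthesis, -0.12 for fatty acid oxidation, -0.12 for glycolysis, -0.063 for oxidative phosphorylation, 0.094 for p53 targets, -0.073 for hypoxia targets and 0.27 for immediate early genes.

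Genes near the end of 19p, and more weakly on 1p, were lower in all 3 labelled lines than in Empty. A trend on GC content, gene length and expression does not account for the 19p shift, since its median was -0.22 (bootstrap SD 0.015) after that trend was removed and -0.24 before. A difference in DNA copy number between Empty and the 3 lines was not decided. At least 90.5% of the 19p genes lay below 0 in each of 3 classes of mean expression, but with 8 genes of the region not below 0 no class could have shown under 80.5%. The medians of these classes, from low to high expression, were -0.24, -0.23 and -0.24. They lay as close together as had been stated beforehand for a copy number difference, but whether another cause would part them was not tested. ZHX3 targeting and a copy number difference cannot be told apart, because all 3 lines shared the shift (highest median -0.18) and there was 1 control line, and DNA was not analysed here.

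Empty stood farther from the labelled lines than these stood from each other, although ZHX3 mRNA did not differ. The smallest mean squared log2 difference beyond error from Empty was 2.06 times the largest between labelled lines, but 1.17 times without Z2 replicate a and 3.61 times without Z2 replicate b, so divergence of the ordinary size between lines cannot be told apart from a larger one. Outside the 2 chromosomal regions Empty had 3.09 times as many called genes as the labelled line with the most, against 3.06 times over all genes. Without Z2 replicate a the values were 1.476 and 1.498, a drop found with and without the regions. The regions hold 165 and 712 of the 15289 tested genes, so these ratios could hardly have come out otherwise. Of the 3911 calls 3593 lay outside the regions, so genes within them make up a minor part of the calls. ZHX3 targeting cannot be told apart from the history of the Empty line, because with 4 lines the control is the farthest with a chance of 0.25 when lines are exchangeable.

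Cell division genes were lower in all 3 labelled lines. Of the 60 members 5 lie in the 2 regions, too few to carry the pattern. The median of -0.35 without those members, against -0.36 for all, was therefore close to fixed in advance. After the trend on GC content, length and expression was removed the median was -0.36, so that trend does not account for the pattern. A different growth state of the wells at harvest cannot be told apart from an effect of the constructs. The Empty mean exceeded that of the highest other line by 0.33 log2 units, while Empty wells themselves ran as widely, from 0.11 to 0.44.

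Random regroupings show what the groups themselves contribute. Of 100 regroupings of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many as 3911 genes for the mean of the 3 lines against Empty (highest other 188). The 1343 shared genes were likewise reached by 1 (highest other 0). No other of these regroupings had the 3 Empty wells as the control, so both counts restate that the Empty wells differed from the rest. Wells of 1 line are not independent lines, so these shares do not exclude a chance difference of the Empty line. With the Empty wells kept together and the 9 others regrouped, 1 of 100 gave as many shared genes, and the other regroupings gave 893 to 1297. All of them kept the same Empty wells as the control, so most of the sharing was built in. The real count ran from 722 to 1813 with 1 library left out, so the gap from 1297 to 1343 does not exclude chance. For single lines against the rest the regroupings of all 12 libraries gave as many in 1 of 100 for Z2 (1277, highest other 91), 3 of 100 for Z5 (128, highest other 745) and 2 of 100 for Z9 (1208, highest other 3453). Most of them spread the Empty wells over several groups, which leaves few calls. In the regrouping with 3453 that group was the 3 Empty wells, which is a structure of the samples, while its 745 belonged to a mix of Z2 b, Z2 c and Z9 c. With the Empty wells kept together and the 9 others regrouped, 4 of 100 gave as many for Z2 (highest other 2142). The same was true of 3 of 100 for Z9 (highest other 2130) and 16 of 100 for Z5 (highest other 2016). These shares compare only groups that carry the same line's name. Which name a group carries is arbitrary, and wells that are not 1 line reached 2016 or more under each name. Chance therefore cannot be excluded for any of the 3 lines. The regroupings with 2142, 2016 and 2130 each had Z2 b, Z2 c and Z5 c as that group, so they are 1 set of wells, singled out after the values were seen. What sets these wells apart was not tested. Chance cannot be excluded for the number of shifted lists: 28 of 100 regroupings gave 8 or more, and the highest other gave 17. Each pair of lines allows 10 splits, too few for a share under 0.05. In fits of those 6 libraries the real split called 2390, 3317 and 3843 genes for Z2, Z5 and Z9 against Empty, 1 for Z5 and Z2, 32 for Z9 and Z2 and 664 for Z9 and Z5, each the 1 split with that many, and the highest other called 0 in each.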

How the results depend on the processing

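The alternatives were fixed before the data were examined, except for the counts without the 2 chromosomal regions. With DESeq2 size factors, without the low-count filter, with the minimum of 1 CPM in 3 libraries and without the 2 regions, the counts of genes stayed within 1.5 times those reported, and so did the number of lists, which was not run without that filter, and all ZHX3 fold changes kept their side of the threshold under every alternative run on them. The lists numbered 9 with that minimum, where WNT targets passed, and 7 without the 2 regions, where complement did not. The DESeq2 Wald test called 11 genes between Z5 and Z2, 1526 between Z9 and Z2, 504 between Z9 and Z5 and 307 for Z5 against the rest. With a 2-fold minimum the counts were 414, 318 and 347 for Z2, Z5 and Z9 against Empty, 369 for their mean, 204 in all 3 lines, 22 between Z9 and Z2, 5 between Z9 and Z5, and 45, 16 and 50 for Z2, Z5 and Z9 against the rest, since fewer genes can qualify. In fits of only the groups compared, Z2 against Empty gave 2390 genes, Z9 against Z2 32 and Z9 against Z5 664. Wells summed per line gave 1100 genes for the mean of the 3 lines, from fewer samples, and 7 lists, where complement (camera adjusted p = 0.0570) and cholesterol biosynthesis (camera adjusted p = 0.0633) missed the threshold and neural markers passed it (camera adjusted p = 0.0455). With an estimated correlation camera called 0 of 40 lists, and fry 24 by its directional p. The cause of the other shifts was not tested.

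The replicate letters were not taken to pair the wells, since the labels tie no letter to a shared day or batch. Over 18 pairs of same-letter wells of different lines, correlations of deviations from the line mean ran from -0.10 to 0.17 (median 0.065), with 5 above 0.1. Over 36 pairs of different letters the median was -0.045, with 2 above 0.1. Same-letter wells were thus slightly more alike, and a shared effect of the letters was not excluded. The likeness was clearest for letter a, where pairs ran from 0.039 (Empty and Z9) to 0.17 (Z2 and Z9). Pairs of b wells or of c wells ran from -0.10 (Empty c and Z9 c) to 0.14 (Empty b and Z2 b). With the letter as a replicate block, 4173, 2823 and 3407 genes differed for Z2, Z5 and Z9 against Empty, 1512 between Z9 and Z2, 488 between Z9 and Z5, 2043 for Z2 and 327 for Z5 against the rest; the counts against Empty and the others stayed within 1.5 times.

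Leaving out 1 library in turn gave 2130 to 4411 genes for Z2, 1087 to 3267 for Z5, 1720 to 4048 for Z9 and 2107 to 4787 for their mean against Empty; 722 to 1813 in all 3 lines; 1 to 153, 75 to 2399 and 37 to 653 for Z5 and Z2, Z9 and Z2, and Z9 and Z5; and 273 to 2955, 38 to 252 and 423 to 1677 for Z2, Z5 and Z9 against the rest. The ZHX3 log2 fold change of Z5 ran from -0.016 to 0.0057 and so changed sign without Z5 replicate b, never passing the test. List counts ran from 8 to 10, and each of the 8 lists passed every time. Of the 168 named genes none changed direction in the mean of the 3 lines. Those called in the mean of the 3 lines numbered 164, of which 32 were not past the test when 1 library was left out, each of them without at least 1 Empty library, and 99 were past it with the lines as units. Without the low-count filter ANKRD1 and RPS4X lost their call. With a total of 50864744 to 65428204 counts per library, INSIG1, SYT1 and HIST1H2AG had 5, 6 and 14 counts over the Empty wells, which leaves their fold changes loose.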

Other observations

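Principal component 2, with 14.7% of the variance, set Z2 b (32.5) apart from the other wells, which lay between -22.0 and 9.28. In counts of reads, Z2 b differed from Z2 a by 44.4 and from Z2 c by 31.1 times sampling noise, where the other pairs of wells of a line differed by 6.17 to 20.2 times.

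The median of the 19p region was lower in Z2 than in the other 2 labelled lines, an observation made after the data were seen. For its 124 genes the median log2 difference was 0.092 for Z5 minus Z2, with 18.5% below 0, and 0.11 for Z9 minus Z2, with 22.6% below 0. For Z9 minus Z5 it was 0.014, with 43.5% below 0. By edgeR 0 of these genes were called for Z5 minus Z2 (25 had an unadjusted p under 0.05), 5 were higher and 1 lower for Z9 minus Z2, and 1 was lower for Z9 minus Z5.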
